A study of Homo sapiens with 8 samples.

How the data were processed

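The data were RNA sequencing read counts per gene from A2780 and ES2, a pair of established human ovarian cancer cell lines. Each line was grown for 48 h without drug, with annonacin, with carboplatin or with both drugs, which gave 8 groups of 1 library each. Per the labels, polyadenylated RNA was selected, a strand-marking dUTP library was made, and read pairs of 150 bases were sequenced. The labels gave no drug doses, stated no batch, and named a pair of different sequencers in different places. A source field that repeated A2780 for the ES2 samples was set aside in favour of the sample titles.

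The deposited values came as whole-number counts per gene and as FPKM (fragments scaled to gene length and library total) made by the authors from the same reads. Per the labels, the authors trimmed with cutadapt 1.9, aligned with HISAT2 2.2.1 and assembled with StringTie 2.1.6, and they also named DESeq2 and edgeR. The counting tool, its strand setting and any filter were not stated. For genes over 200 counts, the ratio of counts to FPKM was within 2% of the library pair's median for at least 99.9% of genes in each of 28 library pairs, so both columns carried 1 measurement. The processing notes named a mouse build, but all 35480 genes had human Ensembl identifiers. Of these, 33671 were in the human GENCODE 29 annotation, 33639 of them on the same chromosome and 18676 with the same start and end, and positions are given as deposited, on the human GRCh38 assembly. A gene symbol was missing for 9396 of the 35480 genes. Those of them that passed the filter were tested but not named by rule. In each library, 1076 to 1266 genes stood at exactly 4 counts against 652 to 723 genes at 3 and 396 to 448 genes at 5. This is an unexplained step in the deposited counts that affects genes near the detection floor.

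Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The filterByExpr function kept 22360 genes, and libraries were scaled by TMM, with factors from 0.811 to 1.151. An edgeR quasi-likelihood model with cell line and treatment as terms was fitted to all 8 libraries. The line was the block that paired each treated library with its own control, so the 2 lines served as the replicates of a treatment and their disagreement was the error, with 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p of 0.05. The common dispersion was 0.253, a biological coefficient of variation of 0.503. The line difference was tested in the same model with 4 libraries per line.

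Within a line there was 1 library per treatment, so a comparison of libraries had no replicate, and no test was run there. Fold changes there were differences of log2(CPM + 1), with CPM meaning counts scaled to a common library total after TMM, and a gene was counted as 2-fold different when at least 1 CPM was reached in either library. Ratios printed for single genes were ratios of CPM without a pseudocount, with exact 95% binomial intervals. Shares of counts have exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since there were no replicate libraries. Reads from PCR are not independent molecules, so the intervals can be too narrow even for counting error. For a gene at 0 counts the bound was taken at 3 counts in 1 library.

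A total of 28 gene lists were fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Lists were tested across lines by limma's camera with a preset correlation between genes of 0.01, by camera with an estimated correlation, and by fry. Adjustment ran over the lists within a comparison. Within a line, a list was described by its median log2 fold and by the percentile of that median among 10000 random lists matched on expression in 10 bins, which is a description and not a test. Named genes were, for each drug against control, those with a mean of at least 1 CPM that differed the same way in both lines, the 6 higher and 6 lower with the largest smaller change. To these were added the 4 higher and 4 lower genes of each line with at least 5 CPM in the higher library, up to 4 members of each described list with the largest change across lines, and 10 genes chosen in advance. The other comparisons took 4 genes in each direction, and the comparison of lines took 5.

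The fit was tested on simulated data with 200 changed genes. With the dispersion estimated from these libraries, 1.5% of 2-fold, 28.4% of 4-fold and 66.7% of 8-fold changes were recovered among 21239 genes tested, with 72 genes called, 8 of them falsely. With the dispersion capped at 0.01, 92.5% of 2-fold changes were recovered.

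Alternatives were DESeq2, median-of-ratios scaling, no filter, a mean of at least 5 CPM, no block for the line, a factorial model, a pseudocount of 0.1 CPM, and each library left out in turn. Alternatives chosen after seeing the data were limma on log2(FPKM + 1), mitochondrial genes left out, library size as the only scaling, ES2 annonacin and ES2 combination left out together, and a term for the split of libraries described in the results. Library size alone moved the median of all genes over control by -0.179 in ES2 annonacin and by -0.193 in ES2 carboplatin on the log2 scale, so folds were read relative to the median gene under TMM.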

Results

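Gene expression was measured by sequencing polyadenylated RNA from 2 ovarian cancer cell lines after 48 h with annonacin, carboplatin, both drugs or neither. Annonacin is an acetogenin from Annona plants that inhibits complex I of the mitochondrial respiratory chain. Carboplatin is a platinum drug that crosslinks DNA. A2780 is an ovarian carcinoma line widely used as platinum-sensitive, and ES2 is a line derived from an ovarian clear cell carcinoma. There was 1 library per line and treatment, so values for a single library have no replicate error. The control library of a line was shared by its 3 treatment comparisons.

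Library totals lay between 51381518 and 67793161 counts. In A2780 they were 56229963 for control, 56132640 for annonacin, 61610381 for carboplatin and 53183825 for the combination. In ES2 they were 55916920, 51381518, 65738296 and 67793161 in the same order. Between 23419 and 25411 genes had counts above 0, and the 10 most counted genes held 7.18% to 11.35% of the counts.

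The libraries of each line fell into pairs that did not follow 1 drug across both lines. In A2780, the carboplatin and combination libraries were nearly alike, with 0.85% of genes differing 2-fold or more and a Spearman correlation of 0.991 across genes. In ES2, the closest pair was annonacin and carboplatin, with 0.85% of genes and a correlation of 0.992. The ES2 combination library stood closest to the ES2 control, with 1.99% of genes differing 2-fold or more. The most distant pair was control and combination in A2780, at 23.15%. These pairs are measured values, and genes are not independent replicates.

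**Figure D1:**
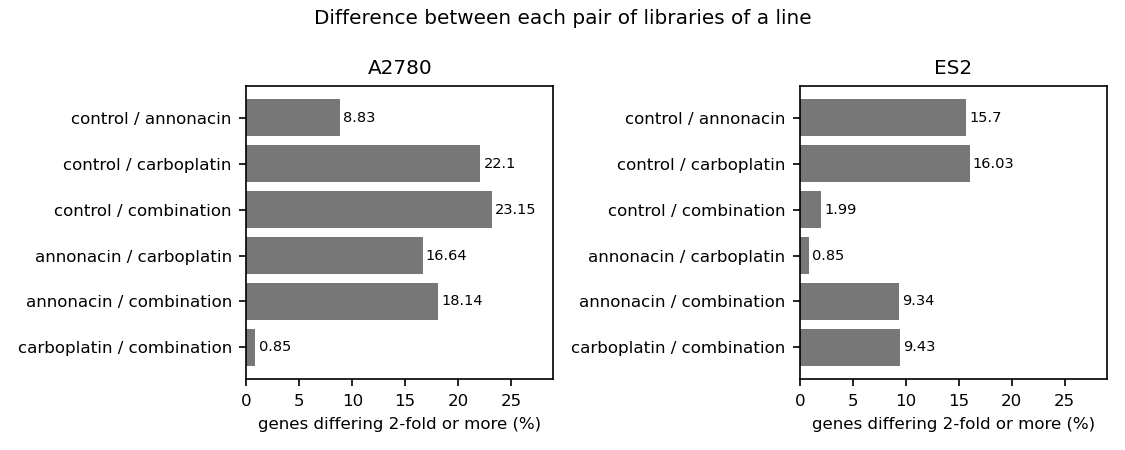
Bars give the percentage of genes differing 2-fold or more (x axis) between the 2 libraries named on the y axis, for A2780 (left) and ES2 (right), 1 library per treatment. The shortest bars, both 0.85%, are carboplatin with combination in A2780 and annonacin with carboplatin in ES2.

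Transcripts encoded by the mitochondrial genome followed the same grouping. Genes on that chromosome held 8.179% of counts in A2780 control (8.171% to 8.186%), 10.422% with annonacin (10.414% to 10.43%), 4.07% with carboplatin (4.065% to 4.075%) and 4.423% with the combination (4.417% to 4.428%). In ES2 the shares were 6.707% in control (6.701% to 6.714%), 3.618% with annonacin (3.613% to 3.623%), 4.066% with carboplatin (4.061% to 4.07%) and 5.496% with the combination (5.491% to 5.502%). MT-CO3, a subunit of cytochrome c oxidase, stood at 6840 CPM in A2780 control and 7710 CPM with annonacin, against 400 CPM with carboplatin and 421 CPM with the combination. In ES2 it stood at 4950, 831, 797 and 3040 CPM in that order. MT-ATP6, a subunit of ATP synthase, stood at 5420, 5710, 269 and 275 CPM in A2780 and at 3580, 672, 685 and 2470 CPM in ES2. The ribosomal RNA MT-RNR2 was higher in the 3 treated libraries of both lines, with 3980 CPM in A2780 control against 8910 to 11200, and 11800 CPM in ES2 control against 14100 to 18400. MT-RNR1 was also higher, with 430 CPM against 723 to 811 in A2780 and 1070 against 1290 to 3760 in ES2. The libraries were made by poly(A) selection, which also sets how much of these short-tailed RNAs is captured.

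**Figure D2:**
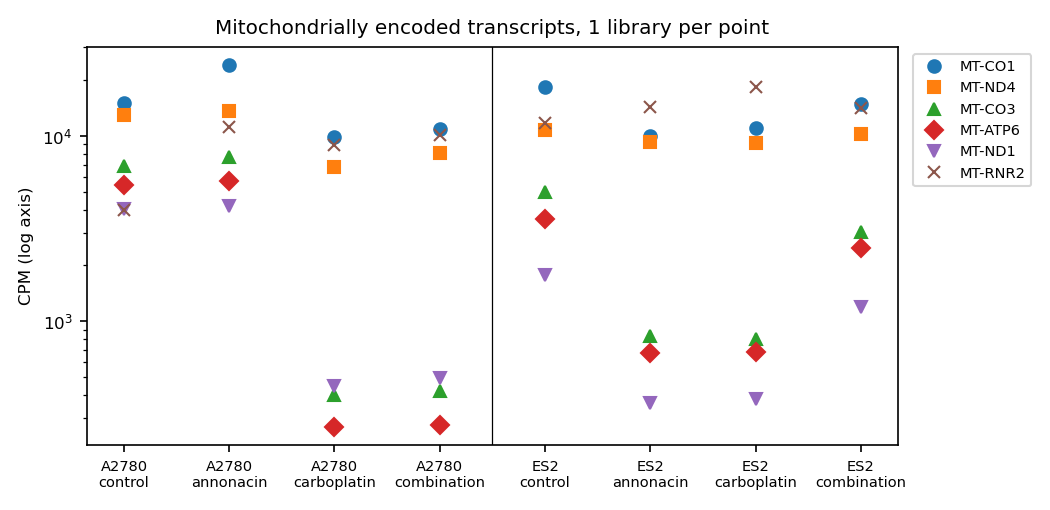
Each point is the CPM of 1 mitochondrially encoded transcript (log y axis) in 1 library (x axis); there are no replicates, so no error bars are drawn. MT-CO3, MT-ATP6 and MT-ND1 are lowest in A2780 carboplatin, A2780 combination, ES2 annonacin and ES2 carboplatin.

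The comparison of annonacin with control asked what the complex I inhibitor does to expression in each line. In both lines DDIT4, a stress-induced inhibitor of mTOR signalling, was higher with annonacin, 5.07-fold in A2780 (69.5 to 352 CPM, counting interval 4.9 to 5.23) and 8.7-fold in ES2 (26.9 to 234 CPM, 8.23 to 9.19). SAT1, which acetylates polyamines (chromosome X, 23783173 to 23786210), was 4.55-fold and 3.75-fold higher. The transcriptional repressor BCL6 was 3.52-fold and 6.7-fold higher, and CCNG2, an unconventional cyclin linked to cell cycle arrest, was 3.17-fold and 4.35-fold higher. KLHL24 and CREBRF were 4.96-fold and 4.63-fold higher in A2780, and 4.08-fold and 4.03-fold higher in ES2. Lower in both lines were CCNE2, a cyclin of S-phase entry, at 0.343 and 0.222 of control, UMPS, an enzyme of pyrimidine synthesis, at 0.428 and 0.314, GPATCH4 at 0.4 and 0.344, and HIC1 at 0.355 and 0.251. SENP3-EIF4A1 and CDRT4 were also lower, but SENP3-EIF4A1 is a read-through of neighbouring genes whose counts depend on how shared reads were assigned. The rises of BCL6, SAT1 and KLHL24 were not particular to annonacin. In A2780 control, annonacin and carboplatin, raw counts were 491, 1717 and 2432 for BCL6 and 395, 1781 and 3606 for SAT1. KLHL24 had 318, 1566 and 5671 there. The same ES2 libraries held 3503, 18391 and 21144 counts of BCL6 and 2864, 8414 and 10444 of SAT1. For KLHL24 they held 1007, 3217 and 3883.

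Stress genes were compared with annonacin in each line, and the difference between the lines was not tested. Of 35 genes of the integrated stress response, the ATF4-driven programme for amino acid and mitochondrial stress, 25 were at least 2-fold higher in A2780, where the list's median log2 fold was 1.35 (percentile 100 of random lists). In ES2 the median was -0.22 (percentile 0.02), with 4 members higher and 4 lower. FGF21, a stress hormone, was 57.0-fold higher in A2780 (0.206 to 11.7 CPM, counting interval 33.1 to 108) and had 0 counts in ES2. SLC7A11, the cystine importer, was 13.5-fold higher in A2780 and stood at 0.824 of control in ES2. INHBE, a hormone subunit induced by ATF4, was 51.5-fold higher in A2780 and stood at 0.0845 of control in ES2, from 2.76 CPM. ASNS, asparagine synthetase, was 4.57-fold higher in A2780 and at 0.427 of control in ES2, and TRIB3 was 3.17-fold higher and at 0.363. PPP1R15A, which reverses the translational block of this response, was 2.15-fold and 7.68-fold higher, and DDIT3 was 3.5-fold and 2.74-fold higher. ATF3 was 6.83-fold higher in A2780 and 1.09-fold in ES2.

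Genes activated by p53 had a median log2 fold of 0.83 in A2780 (percentile 100), with 13 of 30 members at least 2-fold higher. In ES2 the median was 0.10 (percentile 73.99). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, went from 24.7 to 86.4 CPM in A2780 and from 4.06 to 3.08 CPM in ES2. GDF15, a secreted stress cytokine, was 8.39-fold higher in A2780 and 1.62-fold higher in ES2. MDM2, the ubiquitin ligase of p53, was 1.64-fold and 1.62-fold higher.

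Interferon-stimulated genes had a median of 1.46 in A2780 with annonacin (percentile 100), and 25 of 36 members were at least 2-fold higher. OAS2, an antiviral RNA sensor, went from 20.9 to 112 CPM, XAF1 was 6.64-fold, RSAD2 5.33-fold and IFI44L 8.36-fold higher. In ES2 the list's median was -0.19 (percentile 7.81), and XAF1 and RSAD2 had 0 counts there. Fibroblast markers, which A2780 expresses itself, were also higher in that library, with a median of 0.87 (percentile 100) and COL3A1 at 2010 CPM against 916. Immune cell markers had a median of 0.13 (percentile 80.76) in it and of 0 in ES2.

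The 38 DNA replication genes had a median of -0.68 in A2780 (percentile 0, 8 members at least 2-fold lower) and -0.01 in ES2 (percentile 10.4). FEN1, a flap endonuclease, stood at 0.386 and 0.58 of control. The 37 mitosis genes had a median of -0.40 in A2780 (percentile 0.01) and 1.28 in ES2 (percentile 100), where 29 members were at least 2-fold higher, a difference between the lines that was not tested. CDK1, the mitotic kinase, was 3.66-fold higher in ES2 and stood at 0.718 of control in A2780. CCNB1, its cyclin, was 2.3-fold higher in ES2 and stood at 0.582 in A2780. The chaperones of the heat shock list had a median of -0.85 in A2780 (percentile 0) and 1.47 in ES2 (percentile 100). DNAJB1 was 10.9-fold higher in ES2, and HSPA1A and HSPA1B, near-identical copies that share reads, were 18.8-fold and 19.3-fold higher. FOS and ZFP36, immediate early genes, were 45.8-fold and 38.5-fold higher in ES2. NF-kB genes had a median of 0.21 in ES2 (percentile 96.39), where the chemokine CXCL1 was 6.6-fold higher, and of 0 in A2780.

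Nuclear genes of the respiratory chain showed few 2-fold differences, and neither of their lists passed across lines for annonacin (adjusted p 0.141 for complex I and 0.103 for complexes III to V). Complex I subunits had medians of -0.28 in A2780 (percentile 0.17) and 0.20 in ES2 (percentile 88.54), and 0 of the 37 members differed 2-fold in either line. Subunits of complexes III to V had medians of -0.34 (percentile 0.09, 1 of 34 members at least 2-fold lower) and 0.21 (percentile 46.08). The mitochondrially encoded list had medians of 0.08 in A2780 and -1.57 in ES2. Glycolysis genes had medians of -0.45 in A2780 (percentile 0.04) and 0.43 in ES2 (percentile 94.32), with the glucose transporter SLC2A3 9.58-fold higher in ES2. Hypoxia targets had medians of -0.01 and 0.19, and NRF2 targets of -0.28 and 0.19.

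In the edgeR test across the lines 0 of 22360 genes passed for annonacin, with 605 genes at an unadjusted p under 0.05 and a smallest adjusted p of 1. DESeq2 called 10 genes, 8 higher and 2 lower, among them MAPK10 (log2 fold 2.09) and TAGLN (-2.16), and limma on FPKM called 0. When adjusted over the list alone, 1 interferon gene (OAS2, log2 fold 2.05) and 1 epithelial-mesenchymal gene (TAGLN, -2.12) passed, against 0 over all genes. OAS2 had only 11 counts in ES2 control and 24 in ES2 annonacin, so its ES2 side lay near the floor. Of the 28 lists, 8 passed camera with the preset correlation, namely p53 targets (adjusted p 4.8e-06), integrated stress response (9.57e-06), histones (1.75e-05), interferon genes (0.000793), mitosis (0.00182), lysosome (0.00204) and ribosomal proteins (0.033), all up, and DNA replication (9.46e-06), down. None of these calls held with an estimated correlation, where the adjusted p was 0.847 for each, nor did fry call any list. The estimates for these lists ran from 0.14 (lysosome) to 0.83 (mitosis), against the preset 0.01. With correlations of that size the preset p-values are too small. Within lines, ribosomal proteins had medians of 0.11 in A2780 (percentile 99.21) and 0.13 in ES2 (percentile 0.19). Leaving out 1 library ended each of the 8 calls. Without the A2780 control the adjusted p was 0.112 for p53 targets, 0.6 for integrated stress response (turned to down), 0.586 for DNA replication (turned to up), 0.424 for interferon genes and 0.424 for ribosomal proteins. Without A2780 annonacin it was 0.0895 for p53 targets, 0.857 for integrated stress response, 0.196 for DNA replication and 0.0676 for interferon genes (turned to down). Without the ES2 control it was 0.0902 for mitosis (turned to down), 0.138 for histones, 0.162 for lysosome and 0.0615 for ribosomal proteins. Without ES2 annonacin it was 0.0619 for mitosis and 0.0648 for ribosomal proteins (both turned to down), 0.251 for histones and 0.628 for lysosome. The ribosomal call also ended without A2780 carboplatin (0.0867) or ES2 carboplatin (0.469) and with median-of-ratios scaling (0.107). Without ES2 annonacin 1 gene passed, SENP3-EIF4A1 (adjusted p 0.00935).

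**Figure D3:**
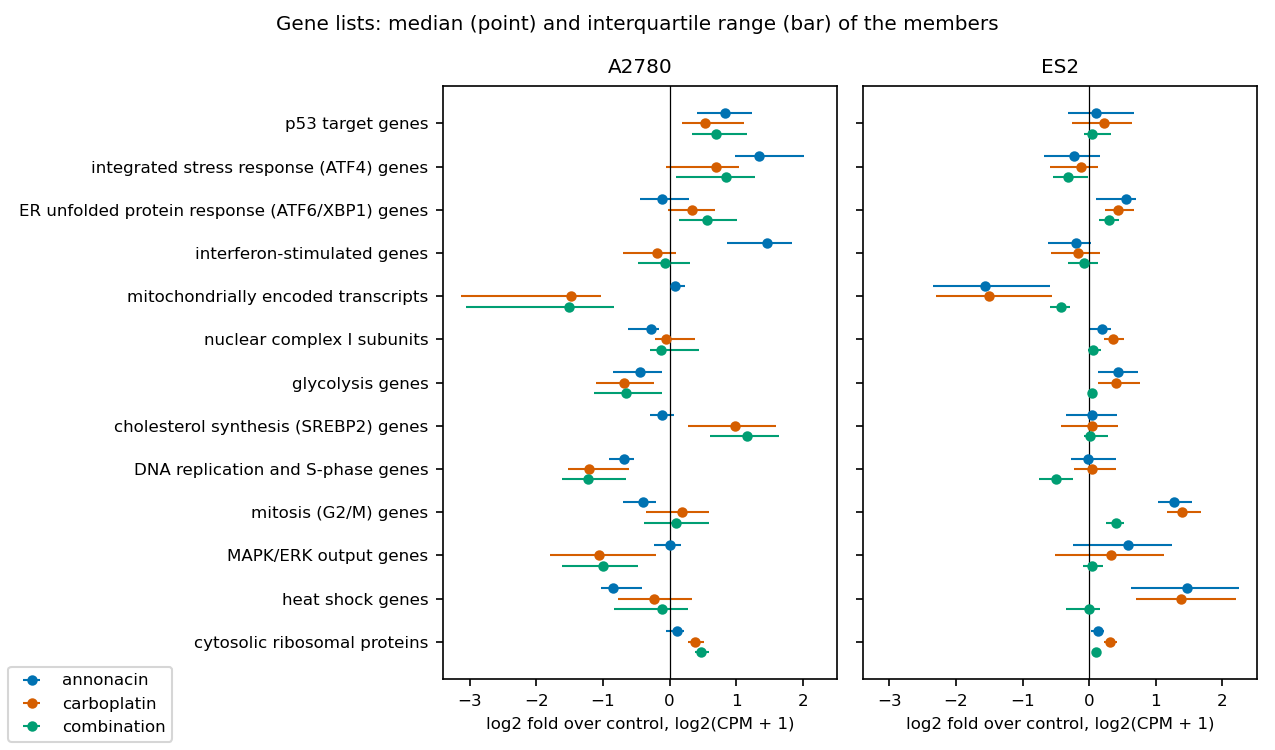
Points are the median log2 fold over control of each gene list (x axis, log2(CPM + 1)) and bars the interquartile range of its members, in A2780 (left) and ES2 (right), 1 library per treatment. Interferon genes reach 1.46 with annonacin in A2780 only among the 6 treated libraries, and mitosis genes reach 1.28 and 1.40 with annonacin and carboplatin in ES2.

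The comparison of carboplatin with control asked what the platinum drug does in each line. PER1, a circadian repressor, was higher in both lines, 6.69-fold in A2780 (52 to 348 CPM) and 7.13-fold in ES2 (33.2 to 236 CPM). YOD1, a deubiquitinase, was 6.04-fold and 13.7-fold higher, MXD1, an antagonist of MYC, 11.3-fold and 6.28-fold, KLHL28 9.97-fold and 7.02-fold, and PPP1R15A 5.74-fold and 7.53-fold. Lower in both lines were the mitochondrial transcripts MT-ND3, at 0.115 and 0.124 of control, MT-CO3, at 0.0585 and 0.161, and MT-ATP8, at 0.0341 and 0.162. MRM2, a methyltransferase of mitochondrial ribosomal RNA, stood at 0.149 and 0.0675 of control, and DERPC at 0.0991 and 0.126. RPL30-AS1 was higher and CDC42EP2 lower in both lines, the former an antisense transcript that overlaps a ribosomal protein gene.

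In A2780 with carboplatin, cholesterol synthesis genes had a median log2 fold of 0.99 (percentile 100), and 12 of 25 were at least 2-fold higher. MSMO1, a sterol demethylase, was 8.45-fold and MVD 5.73-fold higher, and HMGCS1, which makes the precursor of mevalonate, went from 100 to 470 CPM. In ES2 the list's median was 0.04 (percentile 4.32). The DNA replication list had a median of -1.21 in A2780 (percentile 0), with 24 of 38 members at least 2-fold lower, and 0.04 in ES2 (percentile 21.32). MCM3, a subunit of the replicative helicase, stood at 0.373 and 0.498 of control. XRCC2, a gene of homologous recombination, stood at 0.123 and 0.257, and the Fanconi and homologous recombination list had medians of -0.21 and 0.01. Nucleotide excision repair genes had medians of 0.11 and -0.12, with the damage sensor DDB2 2.2-fold and 1.58-fold higher. Immediate outputs of MAPK signalling had a median of -1.06 in A2780 (percentile 0) and 0.33 in ES2 (percentile 72.83). EGR1 went from 178 to 5.31 CPM in A2780 and from 46.9 to 36.9 CPM in ES2, and DUSP6, a feedback phosphatase of ERK, from 124 to 7.51 CPM and from 157 to 472 CPM.

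The p53 targets had a median of 0.53 in A2780 (percentile 99.94, 10 of 30 members at least 2-fold higher) and 0.23 in ES2 (percentile 93.82). CDKN1A was 1.4-fold higher in A2780 and stood at 0.78 of control in ES2, GDF15 was 8.51-fold and 1.67-fold higher, and MDM2 1.62-fold and 1.78-fold. The integrated stress response list had medians of 0.70 (percentile 100) and -0.12 (percentile 0.22), with DDIT3 11.1-fold and 3.03-fold higher and ASNS 4.06-fold higher in A2780 and at 0.48 of control in ES2. Genes of the unfolded protein response had medians of 0.34 (percentile 96.86) and 0.44 (percentile 95.57), with the chaperone DNAJB9 7.2-fold and 3.05-fold higher. Mitosis genes had medians of 0.19 (percentile 91.62) and 1.40 (percentile 100), with the kinase NEK2 2.54-fold and 4.42-fold higher. Lysosome genes had medians of 0.31 and 0.30, with GABARAPL1, an autophagosome protein, 15.0-fold and 2.26-fold higher. Heat shock genes had medians of -0.24 and 1.38, apoptosis regulators of 0 and 0.09, and platinum and drug transport genes of 0.01 and -0.22. In the last group the metal-binding MT1X was 10.1-fold higher in A2780 and 4.27-fold higher in ES2. Outside these lists, genes with large differences of log2(CPM + 1) in A2780 were NGFR, a neurotrophin receptor, from 0.76 to 56.7 CPM, GLIPR1, 49.2-fold, and PIP4P1, a phosphoinositide phosphatase, from 26.2 to 500 CPM.

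In the edgeR test 0 genes passed for carboplatin, with 1794 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.603. DESeq2 called 24 genes, 14 higher and 10 lower, including BCL6 (log2 fold 2.37), SAT1 (2.36), KLHL24 (2.86) and XRCC2 (-2.5), and limma on FPKM called 0. When adjusted over the list alone, 12 of the 15 mitochondrially encoded transcripts passed (smallest adjusted p 0.047), against 0 over all genes, and 10 of those 12 were lower and the ribosomal RNAs MT-RNR1 and MT-RNR2 higher. Of the 28 lists, 10 passed camera with the preset correlation. They were ribosomal proteins (adjusted p 1.24e-10), histones (3.07e-07), mitosis (1.67e-06), lysosome (0.00301), p53 targets (0.00344), unfolded protein response (0.00607), complexes III to V (0.0115) and complex I (0.0133), up, and DNA replication (1.58e-05) and mitochondrial transcripts (0.000758), down. With an estimated correlation, from 0.14 (lysosome) to 0.82 (mitosis) for these lists, the adjusted p was 0.752 or 0.868 and none held. With each library left out in turn, the calls of histones and ribosomal proteins held throughout and the other 8 ended at least once. A term for the library split ended the histone call (0.705). Within A2780 the ribosomal proteins had a median of 0.39 (percentile 100). In ES2 their median was 0.32 at percentile 27.89, so there they rose no more than random lists of like expression. Without the A2780 control the adjusted p was 0.307 for p53 targets and 0.676 for DNA replication, and without A2780 carboplatin 0.113 for unfolded protein response, 0.17 for mitochondrial transcripts and 0.212 for DNA replication. Without the ES2 control it was 0.191 for unfolded protein response, 0.798 for complex I and 0.696 for complexes III to V (both turned to down), 0.0644 for mitochondrial transcripts, 0.943 for mitosis and 0.0644 for lysosome. Without ES2 carboplatin it was 0.0682 for p53 targets, 0.298 for complex I, 0.424 for complexes III to V, 0.118 for mitosis and 0.0612 for lysosome.

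**Figure D4:**
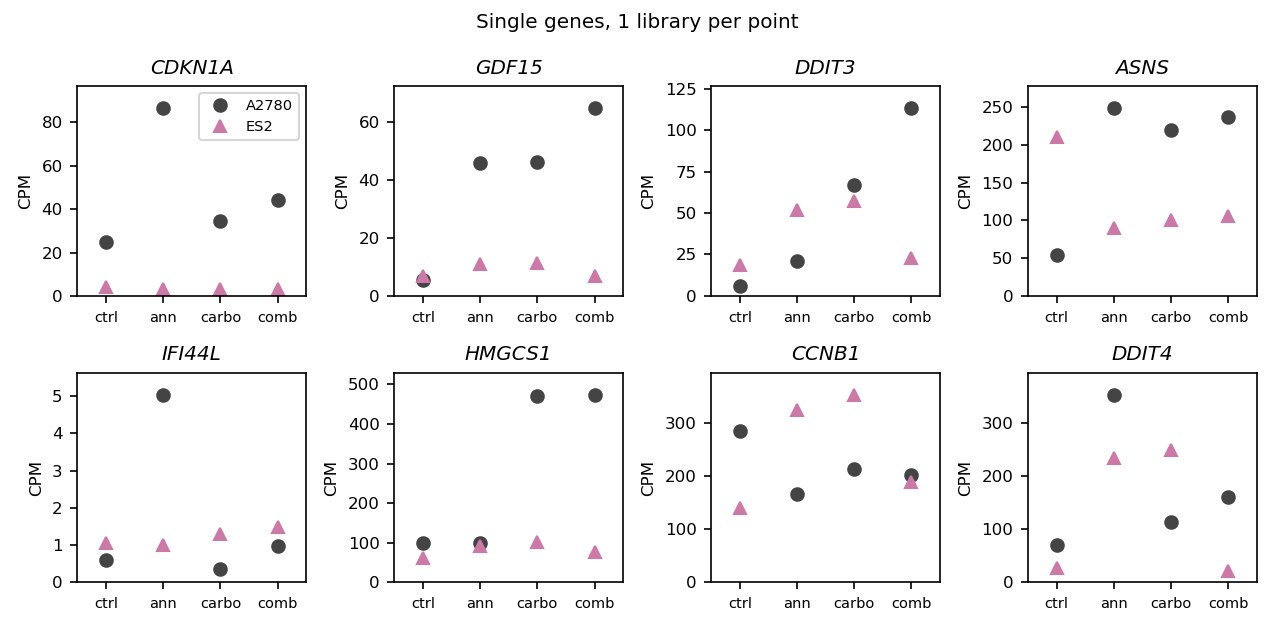
Each point is the CPM of 1 gene (y axis, from 0) in 1 library, with A2780 as circles and ES2 as triangles, under control (ctrl), annonacin (ann), carboplatin (carbo) and combination (comb); there are no replicates. CDKN1A reaches 86.4 CPM with annonacin in A2780 and stays between 3.08 and 4.06 CPM in ES2, and HMGCS1 reaches 470 and 473 CPM with carboplatin and the combination in A2780.

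The comparison of the combination with control asked what both drugs do together. XRCC2 was lower in both lines, from 32.6 to 3.87 CPM in A2780 and from 22.9 to 6.3 CPM in ES2. CCNE2 stood at 0.0673 and 0.184 of control, and CFAP44, CACNG8 and ZNF37BP at 0.114 to 0.19 in A2780 and 0.243 to 0.346 in ES2. Higher in both lines were YOD1, 4.28-fold and 3.63-fold, ZBED6, 2.97-fold and 4.93-fold, and C1QTNF12, 10.2-fold and 2.93-fold. RAB4B-EGLN2, INO80B-WBP1 and CORO7-PAM16 are read-throughs and RUSC1-AS1 is an antisense transcript, so their differences depend on how reads were assigned.

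The DNA replication genes had a median of -1.22 in A2780 and -0.50 in ES2, at percentile 0 in both, with 23 and 4 of 38 members at least 2-fold lower. MCM3 stood at 0.288 and 0.409 of control, MCM10 at 0.25 and 0.4, and FEN1 at 0.172 and 0.652. The Fanconi and homologous recombination genes had medians of -0.48 (percentile 0.26) and -0.29 (percentile 0), with BRCA1 at 0.227 and 0.598 of control. Genes of the unfolded protein response had medians of 0.56 (percentile 99.88) and 0.30 (percentile 99.99), with the chaperone HSPA5 2.05-fold and 1.46-fold higher and HERPUD1 4.9-fold and 1.24-fold higher. Lysosome genes had medians of 0.45 (percentile 99.87) and 0.17 (percentile 98.73), with NEU1, a sialidase, 7.46-fold and 1.18-fold higher. Ribosomal proteins had medians of 0.48 (percentile 100) and 0.10 (percentile 34.62).

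In A2780 the combination library resembled the carboplatin library in the remaining groups. Cholesterol synthesis genes had a median of 1.17 (percentile 100) in A2780 and 0.02 in ES2, and HMGCS1 was 4.72-fold and 1.22-fold higher. MAPK outputs had a median of -1 (percentile 0) in A2780, with MYC at 0.18 of control, and 0.04 in ES2. The p53 targets had medians of 0.70 (percentile 100) and 0.04 (percentile 56.31), with CDKN1A 1.78-fold higher and at 0.795 of control, and GDF15 11.9-fold and 1.01-fold higher. The integrated stress response list had medians of 0.85 (percentile 100) and -0.32 (percentile 0), with DDIT3 18.8-fold and 1.2-fold higher. Interferon genes had medians of -0.07 (percentile 25.03) and -0.08, and mitosis genes of 0.09 and 0.40, the latter at percentile 100. Mitochondrially encoded transcripts had medians of -1.51 and -0.42, at percentile 0 in both.

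In the edgeR test 0 genes passed for the combination, with 755 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.889. DESeq2 called 12 genes, 7 higher and 5 lower, including MCM3 (log2 fold -1.54) and NR2C2 (1.17), and limma on FPKM called 0. When adjusted over the list alone, 1 DNA replication gene passed, MCM3 (adjusted p 0.0276), against 0 over all genes. Of the 28 lists, 10 passed camera with the preset correlation. They were ribosomal proteins (adjusted p 7.07e-11), p53 targets (0.000279), unfolded protein response (0.000279), lysosome (0.000279), cholesterol synthesis (0.000353) and histones (0.00797), up, and DNA replication (5.1e-14), Fanconi and homologous recombination (2.04e-05), MAPK outputs (0.00797) and mitochondrial transcripts (0.00856), down. With an estimated correlation, from 0.05 (Fanconi and homologous recombination) to 0.69 (mitochondrial transcripts), the adjusted p was 0.951 for each and none held. With each library left out in turn, the calls of DNA replication and ribosomal proteins held throughout and the other 8 ended at least once. Without the A2780 control the adjusted p was 0.199 for p53 targets, 0.159 for mitochondrial transcripts, 0.301 for cholesterol synthesis, 0.0521 for Fanconi and homologous recombination and 0.959 for MAPK outputs (turned to up). Without the A2780 combination it was 0.086 for p53 targets, 0.345 for unfolded protein response, 0.713 for mitochondrial transcripts, 0.529 for cholesterol synthesis, 0.888 for histones (turned to down), 0.318 for MAPK outputs and 0.086 for lysosome. Without the ES2 control it was 0.0882 for unfolded protein response, 0.234 for mitochondrial transcripts and 0.627 for histones.

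The combination was also set against each drug alone. Against carboplatin, 122 genes differed 2-fold or more in A2780, 52 of them higher, and 1379 in ES2, 700 of them higher (334 and 2252 genes with a pseudocount of 0.1, and 64 in A2780 with at least 5 CPM in either library). HSPA6, an inducible chaperone, stood at 0.129 of its carboplatin level in A2780 and 0.0163 in ES2, DLEU2 at 0.262 and 0.241, and PYURF at 0.411 and 0.173. ADORA2A, an adenosine receptor, was 7.46-fold and 15.0-fold higher, from 0.268 and 0.15 CPM. Mitosis genes had medians of 0 and -1.05, heat shock genes of -0.07 and -1.57, and DNA replication genes of -0.03 and -0.60 in A2780 and ES2. Paralogous or read-through loci (NBPF19, INO80B-WBP1, HNRNPUL2-BSCL2) also ranked among the largest differences. In edgeR 0 genes passed, with 179 at an unadjusted p under 0.05, DESeq2 called 5, all without a gene symbol, and limma called 0. Those 5 are ENSG00000260772, ENSG00000261054, ENSG00000285269, ENSG00000285830 and ENSG00000287944. The preset camera called 6 of 28 lists, all down, namely mitosis (adjusted p 4.72e-07), DNA replication (1.07e-05), histones (4.1e-05), Fanconi and homologous recombination (8.54e-05), complex I (0.000688) and heat shock (0.00267). With an estimated correlation, from 0.04 (Fanconi and homologous recombination) to 0.83 (mitosis), the adjusted p was 0.948 and none held.

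Against annonacin, the combination differed 2-fold or more in 2725 genes in A2780, 977 of them higher, and in 1372 in ES2, 646 of them higher (in ES2 2229 with a pseudocount of 0.1 and 897 with at least 5 CPM in either library). FOS stood at 0.114 of its annonacin level in A2780 and 0.0253 in ES2, DUSP6 at 0.109 and 0.326, CDK15 at 0.194 and 0.218, and B3GNT2 at 0.386 and 0.355. TAGLN, an actin-binding protein of smooth muscle, was 2.93-fold and 5.14-fold higher, and ZFP69 5.11-fold and 3.73-fold. Interferon genes had medians of -1.47 in A2780 (percentile 0) and 0.11 in ES2, the integrated stress response of -0.89 (percentile 0) and -0.03, and cholesterol synthesis of 1.27 (percentile 100) and 0.08. In edgeR 0 genes passed, with 327 at an unadjusted p under 0.05, DESeq2 called 2 (OAS2, log2 fold -3.17, and ENSG00000287944), and limma called 0. When adjusted over the list alone, OAS2 was the 1 interferon gene to pass (adjusted p 0.00311). In ES2 it had only 24 counts with annonacin and 4 with the combination, near the floor. The preset camera called 10 of 28 lists. They were cholesterol synthesis (adjusted p 1.53e-07), ribosomal proteins (2.78e-07), complexes III to V (4.26e-05), unfolded protein response (0.00554) and complex I (0.0192), up, and DNA replication (2.27e-07), interferon genes (8.86e-05), MAPK outputs (0.000339), Fanconi and homologous recombination (0.000357) and integrated stress response (0.00147), down. With an estimated correlation, from 0.04 (Fanconi and homologous recombination) to 0.7 (complexes III to V), the adjusted p was 0.696 and none held. Without the ES2 annonacin library 1 gene passed, the read-through SENP3-EIF4A1 (adjusted p 0.00958).

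The interaction asked whether both drugs together differed from the sum of their single effects on the log2 scale. TAGLN exceeded that sum by 2.90 in A2780 and 2.49 in ES2, having been lower with each drug alone. KLHL24 (-2.33 and -2.89), SAT1 (-2.04 and -2.98), CREBRF (-2.04 and -3.22) and TXNIP (-2.89 and -2.14), a brake on thioredoxin and glucose uptake, fell short of it in both lines. The A2780 combination library was nearly the carboplatin library (0.85% of genes differing 2-fold or more). In ES2 it was closest to control (1.99%), with annonacin and carboplatin nearly alike. With this pairing, a gene higher with annonacin in both lines would fall short of the sum in both. A gene lower with annonacin would exceed it. The ES2 values also rest on labels whose exchange stays open. In edgeR 0 genes passed, with 765 at an unadjusted p under 0.05, DESeq2 called 13, among them TAGLN (log2 difference 3.48) and BAMBI (-4.65), and limma called 0. When adjusted over the list alone, TAGLN passed in the epithelial-mesenchymal list and the chemokines CXCL1 and CXCL3 in the NF-kB list, the latter with at most 0.113 CPM in A2780 and so measured in ES2 alone. The preset camera called 5 of 28 lists, all down, which were histones (adjusted p 1.68e-07), mitosis (6.61e-07), p53 targets (0.00197), integrated stress response (0.00413) and ribosomal proteins (0.0262). With an estimated correlation, such as 0.37 for histones and 0.83 for mitosis, the adjusted p was 0.933 and none held. Without the ES2 annonacin library 1 gene passed, SENP3-EIF4A1 (adjusted p 0.0157).

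The number of genes differing 2-fold or more from control was 1296 with annonacin, 3269 with carboplatin and 3399 with the combination in A2780, of which 925, 1775 and 1669 were higher. In ES2 it was 2359, 2403 and 293, of which 1068, 1027 and 105 were higher. With a pseudocount of 0.1 the count was 2124 for A2780 annonacin and 762 for the ES2 combination, and with at least 5 CPM in either library the latter was 175. Folds were compared between the lines across 15146 genes, which are not independent replicates, and the lines share no library. The Spearman correlation was -0.135 for annonacin, 0.267 for carboplatin and 0.317 for the combination. Of 177 genes with 2-fold differences in both lines under annonacin, 58 had the same sign (32.8%), against 642 of 747 under carboplatin (85.9%) and 67 of 89 under the combination (75.3%). The A2780 carboplatin folds correlated with the ES2 annonacin folds at 0.276. Correlations between treatments within a line share its control and are not given.

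The lines themselves differed in 8905 of 22360 genes by edgeR, 4670 higher and 4235 lower in ES2, with 11134 at an unadjusted p under 0.05. The direction was not balanced alike under each setting, with 4415 higher and 4479 lower under median-of-ratios scaling, 2853 and 3049 at a mean of at least 5 CPM, 5322 and 5607 in DESeq2, 2763 and 4855 in limma on FPKM, and 2279 and 2295 without ES2 annonacin and ES2 combination. On the ES2 side CPA4, a carboxypeptidase, averaged 1550 ± 74.1 CPM in ES2 (SD, n = 4) and had 0 counts in A2780, at least 28800-fold higher (edgeR adjusted p 8.87e-05). LAMB3, a laminin chain, averaged 544 ± 34 CPM (SD, n = 4, at least 9840-fold), SERPINB2 763 ± 251 (at least 10000-fold), AOX1 433 ± 92.5 (at least 7130-fold) and the chemokine CXCL5 458 ± 205 (at least 5160-fold), each at 0 counts in A2780. On the A2780 side CCND2, a G1 cyclin, averaged 1180 ± 167 CPM (SD, n = 4, at least 14900-fold), the nuclear pore protein NUP210 423 ± 111 (at least 4370-fold), SPOCK2 276 ± 29.8 (at least 3470-fold), LUM, a matrix proteoglycan, 310 ± 157 (at least 2830-fold) and FBXO2 155 ± 41.7 (at least 1400-fold), each at 0 counts in ES2. The edgeR adjusted p of these 10 genes lay between 8.87e-05 and 0.000134.

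Of 24 epithelial-mesenchymal genes, 16 were higher and 3 lower in ES2, or 18 and 4 when adjusted over the list alone. FN1, fibronectin, averaged 1830 ± 408 CPM in ES2 and 1.28 ± 0.641 in A2780 (SD over the treatments, n = 4). CDH2, N-cadherin, averaged 91.7 ± 6.2 and 0.995 ± 0.238. COL3A1 went the other way, with 0.0234 ± 0.0467 CPM in ES2 and 1230 ± 519 in A2780. Of 16 epithelial genes, 6 were higher and 4 lower in ES2, or 6 and 6 when adjusted over the list alone. The keratins KRT7 (226 ± 103 CPM in ES2, 0.0317 ± 0.0633 in A2780) and KRT18 (158 ± 40.9 and 0.06 ± 0.12) were higher in ES2, and the tight junction gene OCLN (2.7 ± 1.33 and 57.5 ± 6.82) was lower (SD, n = 4). The count of 8905 genes was 6180 to 7906 with 1 library left out and 4574 without ES2 annonacin and ES2 combination.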

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

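In this part, the tests of nuclear copies, of a carboplatin response common to both lines and of exchanged ES2 labels were chosen only after the result was seen. The lists below had medians in opposite directions in A2780 and ES2 under the same treatment, both outside the middle 95% of random lists. Other lists also had opposed medians but lay inside that range in ES2. Interferon genes with annonacin had 1.46 in A2780 and -0.19 in ES2 (percentile 7.81). MAPK outputs with carboplatin had -1.06 and 0.33 (percentile 72.83 in ES2). Each line had 1 library per treatment, and the model took the disagreement of the lines as its error, so the difference between the lines was not tested. The 35 integrated stress response genes had A2780 minus ES2 medians of 1.57 log2 with annonacin (1.35 against -0.22), 0.82 with carboplatin (0.70 against -0.12) and 1.17 with the combination (0.85 against -0.32). With annonacin, the 37 mitosis genes differed by -1.68 (-0.40 against 1.28) and the 17 heat shock genes by -2.32 (-0.85 against 1.47). The medians of the mitosis and heat shock lists in ES2 annonacin resembled those in ES2 carboplatin (1.40 and 1.38), the library it was closest to. In ES2 combination they were 0.40 and 0, so with the ES2 annonacin and combination labels exchanged the integrated stress response and mitosis lists would still oppose between the lines and the heat shock list would not.

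Mitochondrially encoded transcripts were lowest in A2780 carboplatin, A2780 combination, ES2 annonacin and ES2 carboplatin (medians -1.48, -1.51, -1.57 and -1.50 against control), and less low in ES2 combination (-0.42, quartiles -0.59 to -0.28), so each library with carboplatin was below its control. The tables argue against reads moved to nuclear copies of these genes, since 4 such copies were also lower in those 4 libraries, with medians between -2.89 and -1.59. Exchanged ES2 labels stay open as a hypothesis: by the correlation of 15110 nuclear genes across the lines, the given labels ranked 12 of 24 assignments (0.031), and the 4 highest, from 0.267 to 0.28, set ES2 combination against A2780 control or annonacin, but fold correlations were mixed, with A2780 combination at 0.317 for ES2 combination and 0.279 for ES2 annonacin by Spearman (0.285 and 0.323 by Pearson), and with A2780 annonacin at -0.015 and -0.135 by Spearman. As labelled, the 15 transcripts stood 0.99 log2 higher (quartiles 0.29 to 1.75) in ES2 combination than in ES2 carboplatin, against a carboplatin response common to both lines and of 1 size, but with ES2 annonacin and combination exchanged (0.267) both of the lowest ES2 libraries would hold carboplatin, so that response stays open too. A response that differs between the lines, unequal poly(A) capture and an unstated batch are also open and were not tested, and no sample was reassigned. The rank of the labels cannot separate exchanged labels from a response that differs between the lines. It largely reflects the same pairing of libraries that raised the question.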

How the results depend on the processing

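Limma on FPKM, a split term, no mitochondrial genes, library size alone, and leaving out ES2 annonacin with ES2 combination were tests chosen only after the data were seen. Each leave-one-out fit leaves an arm with 1 library, which is assumed to vary like the other groups. The edgeR gene counts stayed on the same side under median-of-ratios scaling, no filter, a factorial model, the split term, no mitochondrial genes and limma, with 7591 to 9903 genes for ES2 versus A2780 across treatments (2763 higher and 4855 lower in limma, against 4670 and 4235) and 0 for each drug comparison fitted. Dropping the line block gave 0 genes in all 6 drug comparisons, with 39 to 282 at an unadjusted p under 0.05. DESeq2 called 10 genes for annonacin, 24 for carboplatin, 12 for the combination, 5 against carboplatin, 2 against annonacin and 13 for the interaction, 66 calls in all, 40 of them with a library at 0 counts; the cause was not tested. ES2 versus A2780 across treatments fell to 5902 genes at a mean of at least 5 CPM, where fewer genes were tested, to 4574 without ES2 annonacin and ES2 combination, where fewer libraries were, and to 6180 to 7906 with 1 library left out. Without those 2 ES2 libraries 1 gene passed for annonacin versus control across lines, 1 for combination versus annonacin and 1 for the interaction, each SENP3-EIF4A1 (adjusted p 0.0149, 0.0182 and 0.0309). With 1 library left out these counts were 0 to 1, and 0 for the other 3 drug comparisons. Genes over 2-fold within each line were 2124 for A2780 annonacin versus control, 334 for A2780 combination versus carboplatin, 762 for ES2 combination versus control, 2252 for ES2 combination versus carboplatin and 2229 for ES2 combination versus annonacin at pseudocount 0.1. With at least 5 CPM in either library they were 64 for A2780 combination versus carboplatin, 175 for ES2 combination versus control and 897 for ES2 combination versus annonacin, where fewer genes qualify. Response similarity between lines for annonacin versus control was -0.117 at a mean of at least 5 CPM, and for combination versus control 0.355 there and 0.301 at pseudocount 0.1; the cause was not tested. Gene lists across lines called by camera fell from 49 to 0 with an estimated correlation and were 45 to 61 with 1 library left out. Of 28 list results followed, the split term kept 16, weakened 8 and reversed 4, leaving out both ES2 libraries kept 23, weakened 3 (annonacin lysosome 0.328, carboplatin complex I 0.101 and complexes III to V 0.101) and reversed 2, and median-of-ratios scaling kept 27 and weakened annonacin ribosomal proteins (0.107). With each library left out in turn, 174 of 224 were kept, 40 weakened and 10 reversed. Weakened with the split term were mitosis, histones and lysosome for annonacin, these 3 and mitochondrial transcripts for carboplatin, and histones for the combination. Reversed with the split term were cytosolic ribosomal proteins in annonacin versus control across lines (adjusted p 0.486) and, in carboplatin versus control across lines, ER unfolded protein response (ATF6/XBP1) genes (0.492), nuclear complex I subunits (0.891) and nuclear complex III, IV and V subunits (0.099). Without both ES2 libraries, mitosis (G2/M) genes (0.249) and cytosolic ribosomal proteins (0.543) reversed in annonacin versus control across lines. Those reversed with 1 library left out were, for annonacin, integrated stress response and DNA replication (A2780 control), interferon genes (A2780 annonacin), mitosis (ES2 control, ES2 annonacin) and ribosomal proteins (ES2 annonacin), for carboplatin, complex I and complexes III to V (ES2 control), and for the combination, histones (A2780 combination) and MAPK outputs (A2780 control). Over both directions, adjusted p for annonacin with 1 library left out ran from 5.7e-12 to 0.857 for integrated stress response (ATF4) genes, 4.6e-12 to 0.586 for DNA replication and S-phase genes, 8.14e-09 to 0.0902 for mitosis (G2/M) genes, 1.39e-15 to 0.424 for interferon-stimulated genes and 0.000463 to 0.469 for cytosolic ribosomal proteins. For carboplatin versus control across lines it ran from 6.83e-06 to 0.798 for nuclear complex I subunits and 5.44e-06 to 0.696 for nuclear complex III, IV and V subunits, and for combination versus control across lines from 0.000604 to 0.888 for replication-dependent histone genes and 0.00077 to 0.959 for MAPK/ERK output genes. The cause of these list changes was not tested. Within lines, 168 list medians were the same under median-of-ratios scaling, and 161 were the same and 7 moved at pseudocount 0.1. Of 802 folds of named genes, 53 moved under median-of-ratios scaling, 4 of them across 0 from at most 0.01 log2, and 135 at pseudocount 0.1. Depth limits genes near the floor.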

Other observations

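In this part, the tests of RNA from immune cells, of a response to annonacin also with carboplatin present and of p53 members at 10 CPM or more were chosen only after the result was seen. Of 55 ribosomal protein genes, 39 were higher in ES2 than in A2780 and 0 lower across the treatments (edgeR, 4 libraries per line), or 42 and 0 when adjusted over the list alone. NF-kB genes were 15 higher and 1 lower of 24 (15 and 2 over the list alone), and MAPK outputs 14 higher and 1 lower of 19, the same over the list alone. On the A2780 side were interferon genes, 5 higher and 21 lower in ES2 of 36 (5 and 22), p53 targets, 4 and 19 of 30 (4 and 20), and cholesterol synthesis genes, 1 and 14 of 25 (2 and 14). Of 35 splits of the 8 libraries into 4 and 4, the split by line gave 10634 genes with group as the only term. The highest of the others gave 1. Each other split had both lines in both groups, so the line difference entered its error and lowered its count. The libraries of a line were also its 4 treatments, so the splits cannot exclude chance or an unstated batch between the lines.

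Histone genes, whose mature messengers mostly lack poly(A) tails, had medians of 0.14, 0.39 and 0.31 log2 in A2780 and 0.43, 0.38 and 0.01 in ES2 with annonacin, carboplatin and the combination. On the fitted scale across lines, which the list calls rest on, the medians were 1.60, 2.06 and 1.20, and 24 of the 33 members had a mean under 1 CPM. H2BC11 went from 0.128 CPM in ES2 control to 14.7 with annonacin and 13.9 with carboplatin. HMOX1, a heme-degrading enzyme, was 4.53-fold and 6.49-fold higher with carboplatin and the combination in A2780, and 2.93-fold and 2.88-fold higher with annonacin and carboplatin in ES2. PMAIP1, a pro-apoptotic BCL2-family member, had 0 counts in A2780 and was 2.41-fold and 2.75-fold higher with annonacin and carboplatin in ES2. CIART, a circadian repressor, went from 16.1 CPM in A2780 control to 237 with carboplatin and 277 with the combination. Epithelial genes had medians of -0.28, -0.36 and -0.03 in ES2, where KRT7 stood at 0.473, 0.475 and 0.428 of control.

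Interferon-stimulated genes were higher with annonacin in A2780, with a median of 1.46. The tables argue against RNA from immune cells, whose 14 markers had a median of 0.089 CPM in that library, with CD4 at 4.08, NKG7 at 0.873 and PTPRC at 0.071 CPM (1.867, 0.587 and 0 in A2780 control). A response to annonacin also with carboplatin present stays open, since the list stood at percentile 25.03 in A2780 combination but that was 1 library, seen before the test was chosen. A state of that 1 annonacin culture unrelated to the drug is open too, and replicate cultures of annonacin and the combination in A2780 would be needed to decide.

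The p53 targets were higher in A2780 under each treatment, with medians of 0.83, 0.53 and 0.70, against 0.10, 0.23 and 0.04 in ES2, a difference that was not tested. The tables argue against members shared with the stress lists as the cause, since the 21 other members had A2780 medians of 0.89, 0.59 and 0.59, at percentile 99.84 or above, and ES2 medians of 0, 0.06 and 0. A lower yield of the list in ES2 stays open: 28 of 30 members reached a mean of 1 CPM there, but detection does not bound the yield, since 19 of the 30 were lower in ES2 than in A2780. The 17 members at 10 CPM or more in both controls had medians of 0.70, 0.60 and 0.71 in A2780 and 0.12, 0.41 and 0.05 in ES2, with quartiles that overlapped for annonacin (0.35 to 1.05 and -0.40 to 0.68) and carboplatin (0.30 to 1.12 and -0.35 to 0.62) and did not for the combination (0.32 to 1.19 and -0.04 to 0.30). A working p53 pathway in A2780 and not in ES2 is a hypothesis that was not tested here and would need the sequence of the p53 gene or a p53 knockdown in each line.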
